A study of Daphnia magna with 20 samples.

How the data were processed

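RNA was sequenced from whole Daphnia magna in 20 libraries, 5 in each of 4 groups: control, LCO at 1 mg/L, LCO at 10 mg/L, and lithium and cobalt ions. Per the labels' protocols, each replicate was a pool of 10 daphnids, fed an alfalfa suspension at the start and again during the 48 h exposure, then frozen, and RNA was purified with TRIzol and a spin column before standard Illumina library preparation. Samples were grouped by their titles. Replicate 1 at 10 mg/L was grouped by its title and the series description, which state the dose, although its treatment tag reads untreated. The p-values rest on the spread between these pools. The labels do not say whether each pool was kept in its own vessel.

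The deposited files hold 1 table per library with the same 26646 targets. Estimated counts were deposited, per the file headers, as reads per target that were not normalized, and 87.4% to 90.2% of the values in a library are whole numbers. Fractional values arise where a read is divided between similar targets, and 24.2% of the tested targets held a fractional count in at least 1 library. TPM values were deposited beside them, per the file headers, scaled by effective length and to the same total in each library. Target length and effective length in bases were also deposited. The column names are those of a kallisto abundance table, but the counting program, its version, the annotation and the genome build are not given in the sources used here. None of the target identifiers matched the gene table used here (0 of 26646), so no gene names were assigned.

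Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Targets were kept by filterByExpr with the 4 groups (minimum count 10, minimum total count 15), which left 16163, and libraries were scaled by TMM. All 20 libraries entered a single quasi-likelihood fit with group as the only term, and each of the 5 comparisons was tested two-sided (glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. SEs of log2 fold changes were computed as the size of the log2 fold change divided by the square root of the F statistic. Group means and SDs are of TMM-scaled CPM. The design, the grouping, the rule for named targets and the first 8 of the alternatives below were fixed before the data were examined. The rule named the targets with the smallest p in each comparison, at most 2 higher and 2 lower, for targets without a gene name. Further parts of the rule, 24 preset lists of genes defined by product names and a test of product families needed gene names and were not run.

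No pair of libraries held identical values, and the smallest chi-square per degree of freedom between replicates of a group was 21.5, so each library was counted as a separate replicate. With totals from 20744445 to 44181066 per library, counting error was small beside the spread between pools over the tested targets together. This does not hold for every target with low counts. The fit was tested on simulated counts with 200 changed targets for each comparison. These were drawn from the more abundant targets and were far fewer than the targets called in the data. The rates below therefore do not describe targets with low counts or the real comparisons. For LCO at 10 mg/L against control, on 15775 targets, it recovered 30% of the 1.5-fold changes, 68% of the 2-fold, 90% of the 4-fold and 98% of the 8-fold changes, with 6 false calls among 149.

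Fold changes of comparisons that share the control libraries were correlated across targets. Beside them stand 100 simulated draws with no changed group, in which the controls were simulated too and shared by the comparisons. Also beside them stand 20 splits of the controls, 2 libraries for one comparison and 3 for the other. Overlaps of calls were set beside the number that independent lists of the same sizes would share. Alternatives were DESeq2 1.42.0 size factors in the edgeR fit, the DESeq2 Wald test, no filter on low counts, a mean CPM of at least 5, only the groups compared, the replicate number as a block, limma 3.58.1 on log2(TPM + 1), and leaving out each library in turn. Alternatives added after the data were seen left out the 3 libraries that lay nearer to another group than to their own, or thinned every library to the smallest total, and the split of the controls was also applied to the calls shared by the doses. Figures were drawn with matplotlib 3.10.9.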

Results

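RNA was measured by sequencing in whole water fleas, Daphnia magna, a freshwater crustacean used as a test organism in ecotoxicology. The treatment was lithium cobalt oxide (LCO), a nanomaterial used as the cathode of lithium-ion batteries. Animals that were 5 days old were kept for 48 h in moderately hard water alone (control), in water with LCO at 1 mg/L, in water with LCO at 10 mg/L, or in water with dissolved ions, 66 µg/L lithium as its chloride and 15 µg/L cobalt as its chloride. The ion group carried the amounts that the higher LCO dose releases into water over the same time. Each of the 4 groups held 5 libraries, and each library came from 10 pooled animals. The total estimated count per library ran from 20744445 to 44181066, with group means of 33933028 for control, 30565909 for LCO at 1 mg/L, 34920639 for LCO at 10 mg/L and 24805082 for the ions. Of 26646 transcript targets, 16163 had enough counts to be tested. The deposited tables do not pair target identifiers with gene names, so targets are given by identifier, and position in the genome and gene function are not given. Replicate 1 of the higher LCO dose carries a treatment tag that reads untreated. Its title and the description of the series place it at 10 mg/L, and it lay at a distance of 0.495 from the mean of the other LCO 10 mg/L libraries and 0.916 from the control mean (root mean square difference in log2 CPM, the count scaled to library size, over the tested targets).

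On the first principal component of the log2 CPM values, which held 30.2% of the variance, the mean scores were -57.6 for control, -23.5 for LCO at 1 mg/L, 32.8 for LCO at 10 mg/L and 48.3 for the ions. The ranges overlapped between control (-89.6 to -38.1) and LCO at 1 mg/L (-49.7 to 0.4), and the range of LCO at 10 mg/L (23.9 to 41.5) lay inside that of the ions (10 to 69.5). Of the 20 libraries, 17 lay nearest to the mean of the other libraries of their own group. The exceptions were control replicate 1, which lay nearest to LCO at 1 mg/L, LCO 1 mg/L replicate 5, which lay nearest to LCO at 10 mg/L, and ion replicate 5, which also lay nearest to LCO at 10 mg/L. The median over targets of the SD of log2 CPM within a group was 0.298 in control, 0.231 in LCO at 1 mg/L, 0.224 in LCO at 10 mg/L and 0.327 in the ions.

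**Figure D1:**
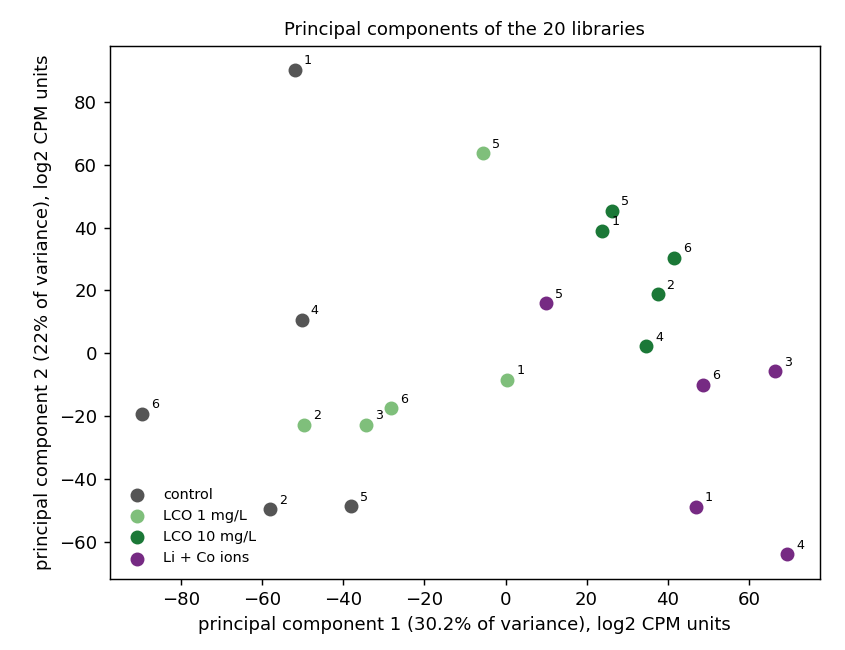
Scores of the 20 libraries on the first principal component (30.2% of the variance) and the second (22% of the variance) of log2 CPM, coloured by group, with replicate numbers beside the points. Control libraries lie on the left (mean score -57.6 on the first component) and ion libraries on the right (mean 48.3), with control replicate 1 and LCO 1 mg/L replicate 5 at the top and ion replicate 5 between the groups.

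The first comparison asked whether 48 h at 10 mg/L LCO changed transcript levels. The higher targets with the smallest p were KZS10867, at 7.97 CPM ± 0.949 against 2.79 ± 0.412 in control (SD, n = 5 each), and KZS10183, at 83.9 CPM ± 10.1 against 38.5 ± 1.62. Their log2 fold changes were 1.52 (SE 0.13) and 1.12 (SE 0.1). The lower targets with the smallest p were KZS13277, at 148 CPM ± 10.1 against 295 ± 7.44, and KZS04441, at 20.6 CPM ± 1.1 against 39.3 ± 1.95, with log2 fold changes of -0.99 (SE 0.08) and -0.93 (SE 0.08). Each of these 4 targets had an adjusted p of 1.9e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and for each no library of the exposed group reached the range of the control libraries. The same test called 4916 targets, 30.4% of those tested, of which 2210 were higher and 2706 lower than in control. Changes over 2-fold were found for 723 higher and 935 lower targets, and changes over 8-fold for 46 higher and 287 lower targets. The values of the exposed and control libraries did not overlap for 20.7% of the tested targets, where chance gives 0.79%. A set of 180 targets was at least 8-fold higher in control replicate 1 than in every other control library, and 53 of these were among the targets called lower at 10 mg/L. Without that library 2 of the 180 were called lower.

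The same question was asked of the lower dose, 1 mg/L. KZS10867 and KZS10183 were again the higher targets with the smallest p, at 7.37 CPM ± 0.485 and 78.9 CPM ± 10.9 (SD, n = 5), with log2 fold changes over control of 1.40 (SE 0.13) and 1.04 (SE 0.1) and an adjusted p of 1.8e-05 for both. KZS04441 and KZS13277 were again the lower targets with the smallest p, at 26.2 CPM ± 2.1 and 199 CPM ± 23.8. Their log2 fold changes were -0.58 (SE 0.08, adjusted p 0.00021) and -0.57 (SE 0.08, adjusted p 0.00043). At this dose 1508 targets passed the threshold, 911 higher and 597 lower, with 328 higher and 118 lower by over 2-fold. The balance of directions depended on the processing, with 1146 higher and 304 lower in limma on log2(TPM + 1), which changed both the measure and the test, and 713 higher and 738 lower at a mean CPM of at least 5. The count fell to 790 without LCO 1 mg/L replicate 1, 911 without its replicate 3, 980 without control replicate 4 and 1005 without control replicate 6.

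Many targets were called at both doses. Of the 911 higher targets, 742 were also higher at 10 mg/L, where independent lists would share 125, and of the 597 lower targets, 510 were also lower, where independent lists would share 100. No target was called in opposite directions at the 2 doses. These lists share the control libraries. With the controls split between the comparisons, an alternative added after the data were seen, the number called in the same direction at both doses was 474 at the median of 20 splits (range 167 to 694), where independent lists would share 63 at the median, and up to 45 targets were called in opposite directions. Fewer control libraries also left fewer calls, a median of 806 at 1 mg/L and 3530.5 at 10 mg/L. The log2 fold changes of the doses correlated across the 16163 targets with Pearson's r = 0.71 and Spearman's rho = 0.74. Targets are not independent replicates, and both comparisons share the control libraries. Simulated groups without change that shared simulated controls gave a mean r of 0.50. The covariance was 0.432, against a simulated mean of 0.07. With the controls split between the comparisons, 2 for one and 3 for the other, the mean r over 20 splits was 0.20, with a range from 0.02 to 0.47. The mean covariance over the splits was 0.147. This fall is larger than the simulated covariance, so the simulation understates what the real shared controls add.

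The third comparison asked whether the dissolved lithium and cobalt changed transcript levels without the particle. The targets with the smallest p were KZS07684, at 812 CPM ± 15 in the ion group against 356 ± 26.3 in control, and KZS07994, at 223 CPM ± 26.9 against 83.8 ± 13.9 (SD, n = 5 each), both higher, with log2 fold changes of 1.19 (SE 0.08, adjusted p 1.3e-07) and 1.41 (SE 0.1, adjusted p 1.5e-07). Among the lower targets they were KZS15444, at 158 CPM ± 20.6 against 378 ± 34.6, and KZS05735, at 251 CPM ± 50.8 against 869 ± 96.2, with log2 fold changes of -1.26 (SE 0.09, adjusted p 1.5e-07) and -1.79 (SE 0.15, adjusted p 4.7e-07). For each of these 4 targets LCO at 10 mg/L lay between control and the ions, with means of 618, 141, 207 and 469 CPM. In total 8100 targets passed the threshold in the fit of all groups, 50.1% of those tested, with 4112 higher and 3988 lower. That fit pools the spread of all groups, and control and ions had the largest median SDs of log2 CPM (0.298 and 0.327). With only the ion and control libraries fitted, 6425 targets passed. Neither direction held a stable majority, and the share of higher targets ran from 46.2% to 56.8% over the alternatives. Of the 8100, 1106 were higher and 1493 lower by over 2-fold, and 26 were higher and 241 lower by over 8-fold. The group values did not overlap for 23.9% of targets, against 0.79% by chance. Of the 180 targets high in control replicate 1, 67 were called lower in the ion group, and 1 without that library.

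**Figure D2:**
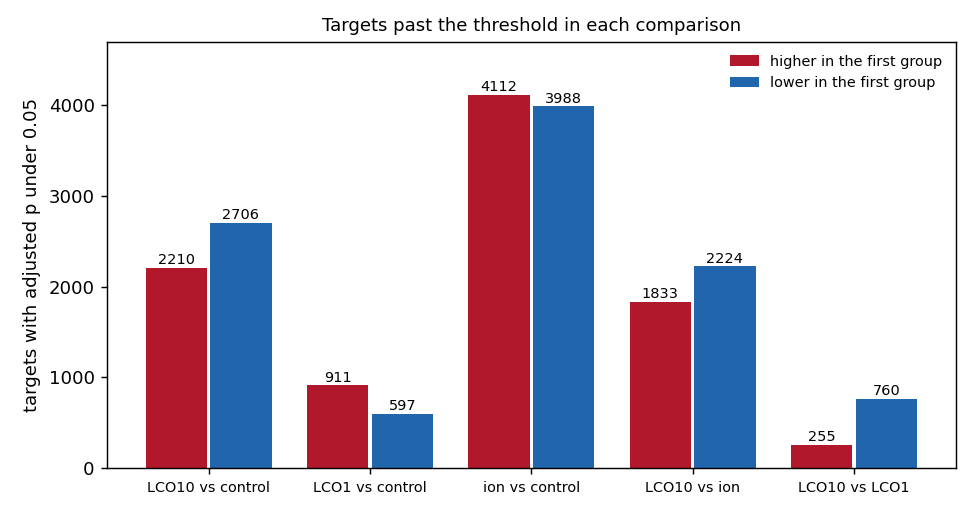
Number of targets with an adjusted p under 0.05 in edgeR's quasi-likelihood test in each of the 5 comparisons, with targets higher in the first group of the comparison in red and lower in blue. The ion group against control has the most (4112 higher and 3988 lower) and the LCO doses against each other the fewest (255 higher and 760 lower).

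LCO at 10 mg/L and the ions moved many targets the same way. Of the 2210 targets higher at 10 mg/L, 1539 were also higher with ions, where independent lists would share 562, and of the 2706 lower targets, 2176 were also lower, where independent lists would share 668. With all controls in both comparisons, 25 targets were higher with LCO and lower with ions, and 7 the reverse. The targets higher with both had median log2 fold changes of 0.62 for LCO at 10 mg/L and 0.78 for the ions, and those lower with both had medians of -0.71 and -0.99. An abundant example, chosen after its values were seen, was the target of rank 21 by mean CPM over all 20 libraries. It stood at 6680 CPM ± 1610 in control, 1550 ± 281 in LCO at 10 mg/L and 2000 ± 741 in the ions (SD, n = 5), with log2 fold changes of -2.11 (SE 0.26) and -1.74 (SE 0.26). The log2 fold changes correlated across targets with r = 0.81 and rho = 0.70. Simulated groups without change that shared simulated controls gave a mean r of 0.50. The covariance was 0.83, against a simulated mean of 0.071. With the controls split, the mean r was 0.45 (range 0.22 to 0.57) and the mean covariance 0.489. Here too the fall was larger than the simulated covariance, which understates what the real shared controls add. Under the same 20 splits the number of shared calls was 2087.5 at the median and 1316 at the lowest, where independent lists would share 620 at the median, and up to 294 targets were called in opposite directions.

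**Figure D3:**
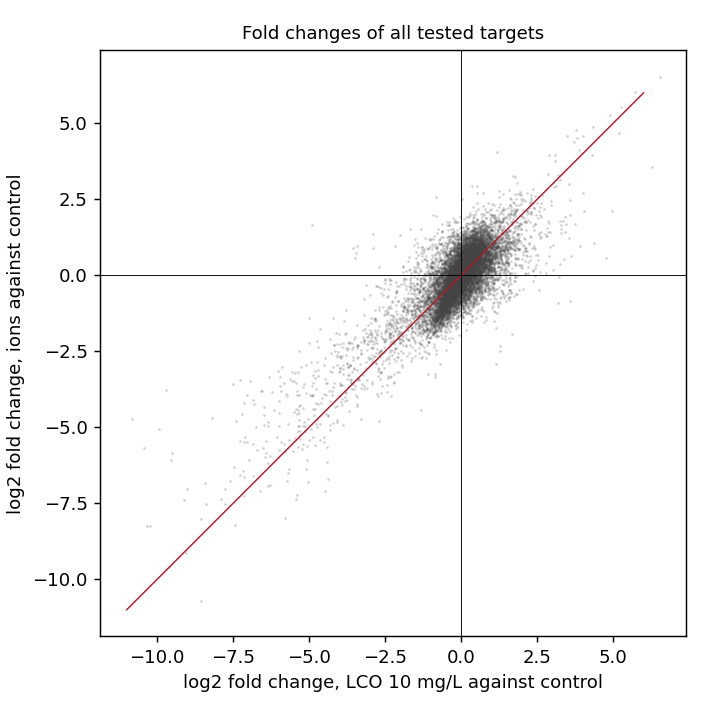
Fitted log2 fold change of each of the 16163 tested targets for LCO at 10 mg/L against control (horizontal axis) and for the ions against control (vertical axis), with the line of equal change in red. Most of the points with large changes lie in the lower left, where both exposures lowered the target, and the correlation across targets is 0.81.

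The fourth comparison set LCO at 10 mg/L against the ions it releases. KZR99914 stood at 2250 CPM ± 500 with LCO and 521 ± 98.3 with ions (SD, n = 5 each), a log2 fold change of 2.11 (SE 0.22, adjusted p 5.2e-05), and at 735 ± 226 in control. KZS18100 was also higher with LCO, at 28.5 CPM ± 3.82 against 11.7 ± 0.888 (log2 fold change 1.28, SE 0.11, adjusted p 1.3e-05). Its control mean was 27.6 CPM, so within this comparison it was the ion group that lay apart. At 1 mg/L it stood at 37.2 CPM, above control by a log2 fold change of 0.43. Its counts were fractional in 16 of the 20 libraries, which makes its level uncertain where reads are shared with a similar target. KZS16074 was lower with LCO, at 64.3 CPM ± 10 against 342 ± 103 (log2 fold change -2.41, SE 0.24, adjusted p 5.2e-05), with a control mean of 44.9 CPM. KZS14686 was also lower with LCO, at 3.17 CPM ± 0.404 against 15 ± 5.71 (log2 fold change -2.23, SE 0.28, adjusted p 0.00019), with a control mean of 16.3 CPM. In all, 4057 targets differed, 1833 higher and 2224 lower with LCO, of which 387 and 501 differed by over 2-fold. Neither direction held a stable majority. Higher targets outnumbered lower ones without a filter on low counts (1837 and 1346), at a mean CPM of at least 5 (2059 and 1862), and without LCO 10 mg/L replicate 1 (1503 and 1493), replicate 4 (1901 and 1759) or replicate 5 (979 and 913), ion replicate 1 (1533 and 1464) or ion replicate 5 (2816 and 2747). Within the calls against control, 911 targets that LCO and ions moved in the same direction also differed between them. The count depended on single libraries. It was 1819 without ion replicate 4, 1892 without LCO 10 mg/L replicate 5 and 2646 without ion replicate 3.

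A group of 259 targets was higher than control at both LCO doses and higher at 10 mg/L than with ions. Its median log2 fold changes over control were 1.08 at 10 mg/L, 1.02 at 1 mg/L and 0.22 with ions. A further 66 targets were lower at both doses and lower than with ions, with medians of -0.89, -0.75 and -0.18. Another class set no condition on the lower dose, so its counts cannot be compared with the 259 and 66. In it, 1576 targets were higher with ions than in control and than in LCO at 10 mg/L. Their median log2 fold change was 0.76 for the ions and 0.15 for LCO at 10 mg/L. A further 1272 were lower (medians -0.89 and -0.32). The classes were defined by the calls, so their medians are partly set by that choice. Ion replicate 5 stood apart within both kinds of target. When sets were chosen without this library, it lay 0.7 above control at the median of 99 targets raised by LCO, in log2 units, while the other ion libraries lay between -0.33 and 0.2. On 395 targets raised by the ions and over 2-fold above both LCO groups it lay at 0.29. The other ion libraries lay between 1.23 and 1.91 there, and the control libraries between -0.73 and 0.84. On 318 targets lowered by the ions and over 2-fold below both LCO groups, ion replicate 5 lay at -0.57. The other ion libraries lay at -1.90 to -1.54 on these, and the LCO 10 mg/L libraries at -0.68 to -0.05. On 698 targets lowered by over 2-fold both at 10 mg/L LCO and with ions, ion replicate 5 lay at -1.24. That was below every control library (-0.46 to 0.44) and above the other ion libraries (-2.34 to -1.92).

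**Figure D4:**
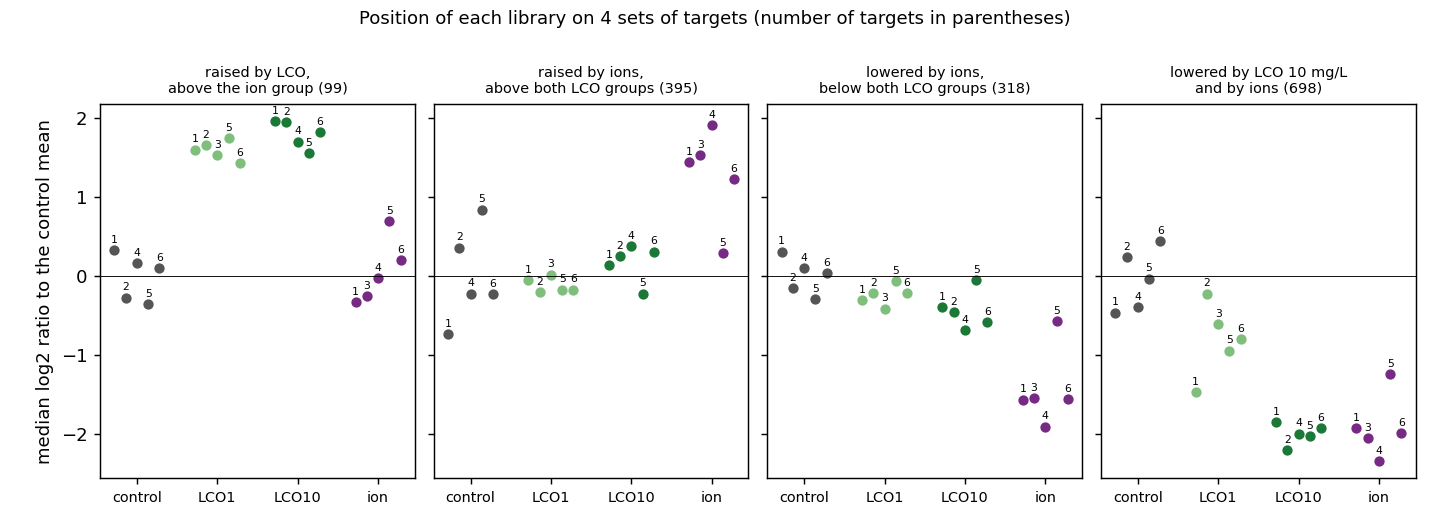
Median log2 ratio to the mean of the control libraries, for each library (points, with replicate numbers) in 4 sets of targets that were chosen by their calls with ion replicate 5 left out, so that the other libraries lie apart partly by construction. Ion replicate 5 lies at 0.7 on the 99 targets raised by LCO and at 0.29 on the 395 targets raised by ions above both LCO groups.

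The fifth comparison asked whether the doses differed. KZS17748 stood at 83 CPM ± 13 at 10 mg/L and 30.1 ± 6.58 at 1 mg/L (SD, n = 5 each; log2 fold change 1.46, SE 0.17, adjusted p 0.00059), and was higher still with ions, at 136 ± 26.1. KZR97950 stood at 113 CPM ± 20 against 41.1 ± 10.3 (log2 fold change 1.46, SE 0.18, adjusted p 0.00076), with 40.8 ± 8.85 in control and 41.3 ± 5.23 with ions. KZS15642 was lower at 10 mg/L, at 26.5 CPM ± 7.99 against 155 ± 52.7 (log2 fold change -2.55, SE 0.3, adjusted p 0.00059), and so was KZS05887, at 11.5 CPM ± 1.61 against 38.2 ± 13 (log2 fold change -1.74, SE 0.23, adjusted p 0.00079). Both of these were also lower with ions than in control, at 48.7 and 12.4 CPM. The doses differed in 1015 targets, 255 higher and 760 lower at 10 mg/L, and by over 8-fold in 4 and 126. Of these, 220 were also higher and 642 also lower at 10 mg/L than in control, and the 642 had median log2 fold changes over control of -1.40 at 10 mg/L, -0.35 at 1 mg/L and -1.13 with ions. The count was 519 without LCO 10 mg/L replicate 6, 522 without LCO 1 mg/L replicate 2 and 580 without LCO 10 mg/L replicate 2. Leaving out the 3 libraries that lay nearer to another group raised it to 1947, and DESeq2 called 1651. LCO 1 mg/L replicate 5 was at least 8-fold above every other library of its group in 198 targets. Without that library the doses differed in 1336 targets, 371 higher and 965 lower at 10 mg/L. Changes over 8-fold between the doses were not counted again without it, so its part in the 126 is not known.

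**Figure D5:**
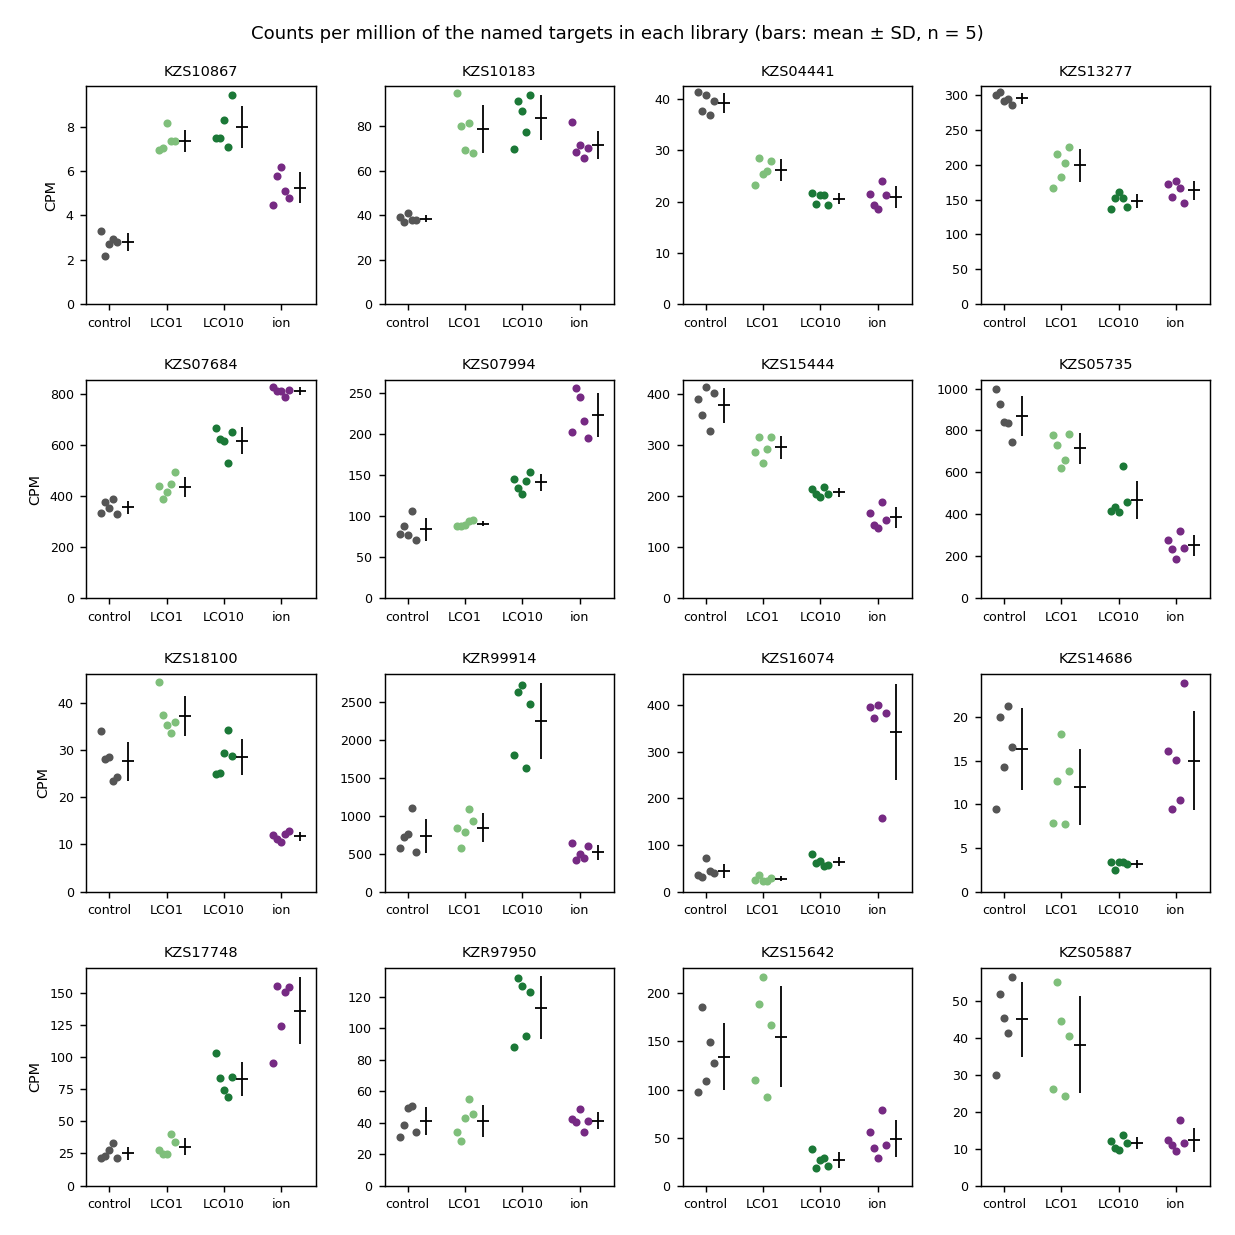
CPM of the 16 named targets in each library (points, by group) with the group mean and SD (black bars, n = 5). KZS10867 and KZS10183 lie above control in all 3 exposed groups, KZR97950 lies apart from the other groups only at 10 mg/L LCO (113 CPM), and KZS16074 is highest in the ion group (342 CPM), with ion replicate 5 below the other ion libraries.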

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

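The tests of label exchange for ion replicate 5 were chosen after the result was seen; the test of RNA mixing and the count of other splits were planned earlier.

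Among 72 groups of 5 values tested for a library far from the rest, 3 passed the critical ratio of 0.71 of the gap to the range, and chance passes about 1 in 20. In KZS16074, ion replicate 5 lay below the other ion libraries with a ratio of 0.923. In KZS05735, LCO 10 mg/L replicate 5 lay above the others (0.742), and in KZS14686, LCO 10 mg/L replicate 2 lay below the others (0.732).

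Several results differed between exposures in a test of the difference itself. LCO at 10 mg/L and the ions differed in 4057 targets, and the doses of LCO in 1015. Of the targets named against control, KZS10867 was higher at 10 mg/L LCO than with ions by a log2 fold change of 0.60. The lower targets named in the LCO comparisons separated the doses, KZS04441 by -0.35 and KZS13277 by -0.42 (10 mg/L against 1 mg/L). The 4 targets named for the ions changed less with LCO at 10 mg/L than with ions and more than at 1 mg/L. KZS07684 differed by -0.39 from the ions and by 0.50 from 1 mg/L, and KZS07994 by -0.67 and 0.63. KZS15444 differed by 0.39 from the ions and by -0.51 from 1 mg/L, and KZS05735 by 0.90 and -0.61.

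For each of the 5 comparisons only 1 of 100 splits of the 10 libraries, the real split, gave as many targets. The other splits were a sample of those possible, so 1 in 100 is the smallest share this test can give. The margin was small for LCO at 10 mg/L against the ions, where a split that was not run may give more. The highest other split gave 1891 against the real 4916 for LCO at 10 mg/L against control, 679 against 1508 for 1 mg/L, 7058 against 8100 for the ions, 3906 against 4057 for LCO at 10 mg/L against the ions, and 1 against 1015 for the doses. The highest other split for the ions against control exchanged control replicate 5 with ion replicate 5, and the highest other split for LCO at 10 mg/L against the ions exchanged LCO 10 mg/L replicate 4 with ion replicate 5.

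Ion replicate 5 carried part of the response that LCO raised and little of what the ions raised above both LCO groups. It carried part of the lowering that both exposures gave (-1.24 in log2 units on 698 targets). Without it LCO at 10 mg/L and the ions differed in 5563 targets. RNA of an LCO library mixed into ion replicate 5 would move it toward LCO by the same share on both sets. Instead, it lay at 0.29 of the way on 99 targets raised by LCO. On 395 targets raised by the ions above both LCO groups it lay at 0.96, a difference of -0.67. The share of 0.29 (interquartile range 0.03 to 0.43) also argues against an LCO library under this label. An exchange with a library of another group needs a partner at the ion level. The nearest, control replicate 5 and LCO 10 mg/L replicate 4, reached only 0.21 on the targets lowered by ions below both LCO groups. Control replicate 5 did reach 0.67 on the targets raised by ions above both LCO groups. A sample from outside the series, a mixture of more than 2 sources, or a pool that responded differently to the ions stays open, and no biological explanation was tested.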

How the results depend on the processing

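Leaving out the 3 libraries nearest to another group, thinning and the split of the controls for shared calls of the doses were chosen after the data were seen. All 380 values of the named targets under the alternatives kept their direction and stayed past the threshold. These targets were chosen by the smallest p in the same libraries, so this was likely from the start and does not speak for other calls. The counts for LCO at 10 mg/L and for the ions against control stayed within 1.5 times. The doses differed in 1015 targets as reported, in 1651 with DESeq2, in 1752 with only the 2 groups fitted and in 1947 without the 3 libraries; the cause was not tested. The replicate numbers showed no consistent pairing of the libraries. Of 25 pairs with the same number, 9 had deviations correlated over 0.1 (median -0.07, range -0.43 to 0.49). The median for pairs with different numbers was 0.01, and 4 of 20 libraries correlated best with their own number. A weaker or partial pairing is not excluded. With the replicate block, 853 targets passed for LCO at 1 mg/L, 2465 for LCO at 10 mg/L against the ions and 593 for the doses, and no other count moved by over 1.5 times. Leaving out each library in turn gave 3902 to 5030 targets for LCO at 10 mg/L, 790 to 2000 for 1 mg/L, 7103 to 8570 for the ions, 1819 to 5563 for LCO at 10 mg/L against the ions and 519 to 1336 for the doses. It gave 2943 to 4058 for the 3715 calls shared by LCO at 10 mg/L and the ions, and 228 to 379 for the 325 changed by both doses and different from the ions. The lowest values came without replicate 1 of LCO 1 mg/L (790), ion replicate 4 (1819) and LCO 10 mg/L replicate 6 (519). With the controls split, the mean correlations of fold changes were 0.45 for LCO at 10 mg/L and the ions, 0.20 for the doses and 0.11 for LCO at 1 mg/L and the ions, against 0.81, 0.71 and 0.58. For LCO at 1 mg/L and the ions the splits ran from -0.17 to 0.38. The value of 0.58 with all controls shared stands beside a simulated mean of 0.50 for unchanged groups with shared controls. That simulated value does not apply to split controls, and splitting leaves fewer control libraries in each comparison. The share of higher targets at 1 mg/L was 60.4% as reported, 72.4% without a filter, 49.1% at a mean CPM of 5 and 79% with limma on log2(TPM + 1), which changed both the measure and the test. For LCO at 10 mg/L against the ions it was 45.2% and, without a filter, 57.7% (52.5% at a mean CPM of 5). For the doses it was 25.1%, with 37.7% at a mean CPM of 5 and 15.9% with limma on log2(TPM + 1). The 24 preset gene lists and the test of product families were not run, because no gene names were matched. Thinned to the smallest total, the ions still gave 7906 targets and LCO at 10 mg/L 4709, so unequal depth changed these counts little. Thinning does not show what greater depth would add.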

Other observations

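The tests of an exchange between control replicate 1 and LCO 1 mg/L replicate 5 were chosen after the result was seen, as were the values for abundant and consecutively numbered targets.

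Targets were ranked by mean CPM over all 20 libraries, so a target raised in some group ranks higher through that change. Among the first 25, 8 were higher and 4 lower at 10 mg/L LCO than in control, 7 were higher and 1 lower at 1 mg/L, and 4 were higher and 2 lower with ions. Over all tested targets 30.4%, 9.3% and 50.1% were called in these comparisons. The target of rank 3, which owes that rank to its level at 10 mg/L, stood at 7350 CPM ± 1910 in control, 8610 ± 2310 at 1 mg/L, 22000 ± 4230 at 10 mg/L and 4170 ± 1510 with ions (SD, n = 5). It was higher at 10 mg/L than with ions by a log2 fold change of 2.40 (SE 0.27, adjusted p 7.1e-05 in edgeR's quasi-likelihood test) and higher than at 1 mg/L by 1.36 (SE 0.26, adjusted p 0.005). The target of rank 4 was higher than in control at both doses, at 13000 CPM ± 966 and 12500 ± 840 against 7490 ± 1270, with log2 fold changes of 0.80 and 0.74, and stood at 9100 ± 855 with ions (adjusted p 0.057). The 5 most abundant targets of a library took 6.53% ± 0.6 of its counts in control, 7.34% ± 0.4 at 1 mg/L, 8.18% ± 0.49 at 10 mg/L and 7.3% ± 0.87 with ions (SD, n = 5).

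Targets with consecutive identifier numbers showed a weak tendency to change in the same direction. Over 12017 such pairs, the log2 fold changes correlated with r = 0.26 for LCO at 10 mg/L against control, 0.17 for 1 mg/L and 0.23 for the ions, while the highest of 1000 shuffles was 0.03 in each. Over the 8111 pairs without fractional counts r was 0.20, 0.14 and 0.17. Spearman's rho over all pairs was 0.16, 0.12 and 0.17. For the ions both targets of 2160 pairs were called in the same direction, where the median shuffle gave 1509. Whether consecutive numbers are neighbours in the genome was not determined.

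More targets passed the threshold with ions than with LCO at 10 mg/L, 8100 against 4916, a ratio of 1.65. A difference in depth does not account for it. The ion group had the lower mean total, 24805082 against 34920639 for LCO at 10 mg/L, which would work the other way. With all libraries thinned to the smallest total the ratio was 1.68. Neither ion replicate 5 nor control replicate 1 alone accounts for it, since the smaller of the ratios without either was 1.59. The range over 29 settings was 1.33 to 2.03. The lowest ratio came with only the 2 groups of each comparison fitted, with 6425 targets for the ions and 4838 for LCO at 10 mg/L. The size of the excess therefore depends on which groups are fitted together. The groups also differed in the form of the metals, dissolved or in particles, and no biological explanation was tested.

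Control replicate 1 and LCO 1 mg/L replicate 5 shared a set of high targets across groups. Control replicate 1 was at least 8-fold above every other control library in 180 targets, LCO 1 mg/L replicate 5 had 198 such targets in its group, and 136 were common to both, where independent lists would share 2.2. On the 180 targets the median was 91.8 CPM in the control library, 34.3 CPM in the LCO library and 0.778 CPM over the other 18. Exchanged labels are argued against by control replicate 1 lying at 0.09 of the way to LCO on 330 targets raised by LCO. LCO 1 mg/L replicate 5 lay at only 0.59 of the way there. Its median log2 ratio to control replicate 1 over the 180 targets was -1.44. Both values would go with some RNA of the control library in it. The SD of 1.4 of the log2 ratios over the 180 targets goes against this, since carried RNA would give a nearly constant ratio. Mixing therefore stays undecided. For target length, rho was -0.08 over all tested targets, which cannot decide on a length bias within the 180. Another candidate explanation that stays open is a shared physiological state of these pools, such as a stage of the moult or reproductive cycle. It was not tested because the targets have no gene names.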
